A study of Mus musculus with 2 samples.

How the data were processed

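RNA from whole mouse hearts was measured on 2 two-colour oligonucleotide arrays, 1 with a pair of control hearts and 1 with a pair of hearts lacking Sirt1 in cardiomyocytes. On each array the heart of a mouse fed freely (ad libitum, AL) carried Cy5, read at 635 nm, and the heart of a calorically restricted mouse (CR) carried Cy3, read at 532 nm, per the labels. The dyes were not swapped on either array. The 4 hearts came from different mice, so each condition was measured in 1 heart. The difference of the responses leaves no residual degree of freedom for a test. A test of CR over AL across both arrays, or of genotype across both diets, would have 1, could not tell diet from dye or genotype from array, and was not run. The number of arrays limits the precision of every value, and no p-value or replicate SD is given.

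The deposited scanner files hold the spot intensity, the median brightness of each spot at both wavelengths, and the median brightness around it, per the file headers. The headers also give line fits that tie scans at higher gain to the lowest gain. The scanner software and a genome build are not given in the sources used here. The authors' deposited table holds log2 ratios of CR over AL, per the labels. It was rebuilt from the scanner files as log2 of the 532 nm over the 635 nm signal, each minus the trimmed mean of the array's blank spots, minus a constant. After subtraction of the constants -0.359 (control array) and -0.144 (knockout array), 17405 of 17405 and 16555 of 16555 values lay within 0.001 of the table. The medians of its columns were -2.885e-06 and 8.079e-05. Its scale, centring and direction were therefore settled and none of them stays unknown. It holds 6068 and 6918 empty values, and the detection rule described here gave the same state for 23469 and 23466 of 23473 probes.

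Spot intensities were corrected with normexp (offset 50) and normalized within each array by loess with limma 3.58.1 in R 4.3.3, with control spots and spots marked by the scanner given weight 0 (1 spot on the control array and 3 on the knockout array were so marked). Normexp was run on the spot signal without the local background. That choice was made after the data were seen: the plan had fixed normexp and its offset and had not said how the local background would be used. The reason was that the brightness around a spot followed the spot's own brightness. The Spearman correlations were 0.875 and 0.888 at 532 nm and 0.936 and 0.944 at 635 nm. Subtracting the local background might thus take away signal as well, but a true background could also give such correlations, and this was not settled. Because several results depend on the choice, subtraction of the local background was added as an alternative, also after the data were seen. Its values are given with many of the results it moved. Loess within each block of the array was the other alternative added then. For comparisons between the arrays, separate channels were taken after Aquantile normalization.

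A spot was called detected where its signal exceeded the mean of the 2736 blank spots, after leaving out 5% at each end, by 2 SD. In the control array 77.8% of probes were detected in the CR heart and 80.7% in the AL heart, and in the knockout array 74.0% and 77.6%. The median signal of detected probes minus the blank mean was 41.8 (CR) and 30.0 (AL) scanner units on the control array and 40.5 and 34.1 on the knockout array. The blank means were 74.9 and 32.45 on the control array and 75.6 and 34.9 on the knockout array. Of 24 spots each of a pair of positive controls, log2 ratios had SDs of 0.048 and 0.060 on the control array and 0.076 and 0.088 on the knockout array, which describes spot noise and not the difference between mice. Before centring, their mean log2 CR over AL ratios were 0.145 and -0.274 on the control array. On the knockout array these means were -0.647 and -0.053. The order of the pair thus changed between the arrays, and the cause was not tested.

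Of 23473 probes, 16631 carried 1 gene symbol in the platform annotation and 6842 carried none and stayed unnamed. Symbols were updated through the gene table of GRCm38.p6, used for names and neighbourhood only: 12622 were current, 3947 were updated through a synonym and 62 did not match. For a gene with several probes the brightest was used. This gave 16390 genes, 11698 of them detected in all 4 channels. A gene detected in 1 channel of an array received only a bound.

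Named genes followed a rule: Sirt1, the 10 highest and 10 lowest for CR over AL on each array, the 6 highest and 6 lowest in the other comparisons, the 6 alike on both arrays in each direction, up to 4 members of each list that stood apart and of both complement lists, and up to 3 bounds each way. The ranked genes had to be detected in all channels, to be at or above the median signal and to have a symbol that is not a clone or model name (5067 genes). For 47 lists (29 pathway and 18 cell-type lists, 881 members besides the ribosomal proteins) the median log2 was set against 10000 random lists of the same size matched on signal in 20 bins. A list was said to stand apart under percentile 2.5 or over 97.5. Lists with under 3 measured members were left out. This removed those of thymocytes and red blood cells (1 and 2 measured members on the control array) and left 45. Of 45 lists of unrelated genes, 2.25 would stand apart in each comparison. Genes of 1 list can vary together between mice, so 2.25 does not gauge the spread between mice. Lists share genes, so they are not independent of each other. The comparisons, the lists, the naming rule, the detection rule and all alternatives but the 2 added ones were fixed before the data were examined.

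The procedure was tested on simulated arrays. Among 15543 unchanged probes none passed 2-fold, on either array. These probes carried random noise and a smooth dye trend only, with SDs of 0.069 and 0.071. Across genes of the real arrays the SDs were 0.182 and 0.194. No probe-specific dye bias or difference between mice was simulated, so the count does not bear on either. For probes at or above the median signal a true 2-fold difference (log2 of 1) was returned as 0.75 on the control array and 0.73 on the knockout array, and 2 of 32 such probes passed 2-fold on each. For dimmer probes it was returned as 0.27 and 0.29 and 0 of 28 passed. The values given are therefore on average smaller than the true differences, most of all for dim genes, and counts past 2-fold miss genes, but single values spread around that average (SD 0.186 and 0.174 for the brighter probes) and can exceed the true difference. Of 300 lists of 15 probes drawn at random from a simulated array 19 stood apart (6.33%), a share that the random drawing itself sets. Of 60 such lists shifted by 0.2 all 60 did. Simulated values spread less than real ones and members of a list did not vary together, so neither share carries over to the real lists.

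Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were no background correction, a normexp offset of 0, median centring in place of loess, the authors' deposited ratios, no detection filter, only genes at or above the median signal, the mean over a gene's probes, median scaling or quantile normalization of the channels, and 1.5-fold in place of 2-fold.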

Results

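Gene expression was compared in hearts of male C57BL/6J mice, 6 months old, after 3 months of free feeding or of caloric restriction by 40%. Control mice and mice without the deacetylase Sirt1 in their cardiomyocytes were studied, which asks how the response of the heart to restriction differs without Sirt1 in its muscle cells. Each array paired 1 CR heart with 1 AL heart of the same genotype, so there were 2 arrays and 4 hearts. Because each condition was measured in 1 heart, no value has a replicate check: every difference describes these hearts and cannot be set against the spread between mice. Values are log2 ratios, and on simulated arrays they were on average smaller than the true differences, most of all for dim genes, although single values, above all those named for being highest or lowest, can also exceed them.

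Sirt1 itself had a log2 signal of 7.11 in the control AL heart and 7.07 in the knockout AL heart, and of 7.53 and 7.51 in the CR hearts. Its CR over AL value was 0.42 on the control array and 0.43 on the knockout array, and the knockout hearts differed from the control hearts by -0.04 under AL and -0.02 under CR. The position of the probe relative to the deleted part of the gene is not known here, and the heart holds cells other than cardiomyocytes, so this value does not check the genotype. The CR over AL values were 0.11 and 0.25 with the local background subtracted, and the differences between the genotypes 0.23 and 0.36.

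In the control hearts, Myh6, the main myosin heavy chain of the adult mouse ventricle, was higher with CR by 1.29, Ankrd1, a stress-responsive nuclear and sarcomeric protein, by 1.23, Ctsl, a lysosomal protease, by 1.08, and Myom2, a protein of the sarcomeric M-band, by 1.03. H2-Aa, an MHC class II chain of antigen-presenting cells, was lower at -1.30, Tyrobp, a signalling adaptor of myeloid cells, at -0.94, Cd52, a surface protein of leukocytes, at -0.93, C3, the central complement component, at -0.92, and Col3a1, a fibrillar collagen, at -0.86. Fabp3, the fatty acid binding protein of heart muscle, was lower at -1.30, with its AL signal near the limit of the scanner. In all, 10 genes were at least 2-fold higher and 3 at least 2-fold lower among 12658 compared (76.9% higher), against 17 and 2 with median centring in place of loess (89.5% higher) and 18 and 33 with the local background subtracted (35.3% higher). In that setting Myh6 was at 0.85, H2-Aa at -0.68, and Nexn, an actin-binding Z-disc protein at 1.27 otherwise, turned to -0.89. Eif3j1, at 1.16 (0.66 with the local background subtracted), had other probes at -0.02 and 0.16.

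Of the 45 lists measured, 14 stood apart on the control array, 4 higher and 10 lower. Lists of unrelated genes would give 2.25, but genes of 1 list can vary together between mice. An excess over 2.25 was therefore not a test of the diet. Nuclear genes of oxidative phosphorylation were lower in 47 of 65 (median -0.22), with Cox8b at -0.77, Cox7c at -0.75 and Ndufv3 at -0.61. Extracellular matrix genes were lower in 24 of 30 (median -0.14), among them the crosslinking enzyme Loxl1 at -0.69, fibronectin (Fn1) at -0.50 and the proteoglycan biglycan (Bgn) at -0.45, and beside them fibroblast markers were lower in 12 of 14 (median -0.38). MHC class II genes were lower in 3 of 4 (median -0.42), and macrophage markers in 9 of 12 (median -0.09). Clock genes driven through E-boxes were higher in 10 of 12 (median 0.27), with the deubiquitinase Usp2 at 0.70, Ciart at 0.53 and Dbp at 0.45, whereas Arntl, which drives them, was at -0.42. Antioxidant genes were higher in 16 of 23 (median 0.14), including Gclm at 0.67, Nqo1 at 0.60 and the glutathione transferase Gsta3 at 0.56, but the uncoupling protein Ucp2 was at -0.62. Glucocorticoid-responsive genes were higher in 12 of 17 (median 0.15) and hypertrophy genes in 12 of 18 (median 0.12). Angiogenesis genes (12 of 20 lower, median -0.11), ribosomal proteins (36 of 52 lower, median -0.07), markers of epicardium and mesothelium (4 of 5 lower, median -0.13) and of lung epithelium (5 of 5 lower, median -0.10) were the remaining lists besides complement. The glucocorticoid, angiogenesis and macrophage lists no longer stood apart with the local background subtracted (medians 0.02, -0.00 and -0.01), and the hypertrophy list did not under 4 alternatives. Of the genes named here, Cox7c was then at -1.69, Ndufv3 at -0.15, Loxl1 at -0.32, Ciart at 0.29, Gsta3 at 0.33 and Arntl at -0.25.

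Complement genes were followed because the study is known to have picked them from these arrays, so their counts are not independent evidence. Complement components were lower with CR in 12 of 17 on the control array (median -0.07, percentile 0.770) and in 15 of 19 on the knockout array (median -0.10, percentile 0.01). C3 went from a log2 signal of 8.65 in the control AL heart to 7.73 in the control CR heart, while in the knockout hearts it was 8.55 and 8.41, a CR over AL value of -0.14. The knockout response of C3 minus its control response was thus 0.78. The chains of C1q, which starts the classical pathway, ran the other way and were lower on the knockout array, with C1qa at -0.33 in control and -0.79 in knockout hearts, C1qb at -0.58 and -1.05, and C1qc at -0.32 and -0.67. Markers of macrophages, which make C1q, were also lower on the knockout array (10 of 11, median -0.28) and in the difference of the responses (median -0.20). For the components as a list the difference of responses did not stand apart (median -0.06, percentile 7.80), but it did with a normexp offset of 0 (-0.26), in the authors' deposited ratios (-0.37) and among genes at or above the median signal (-0.31). Complement regulators did not stand apart on the control array (median 0.12) or the knockout array (median 0.01), with Serping1, an inhibitor of C1, at -0.57 and -0.31 and clusterin (Clu) at 0.43 and 0.78. In the difference of the responses the regulators did, lower in 5 of 8 (median -0.18, percentile 0.19), but the median was 0.04 with the local background subtracted. Between the genotypes the components stood apart higher in the knockout hearts under AL (median 0.07) and CR (median 0.13). The regulators did so under AL (median 0.18, or -0.10 with the local background subtracted). With the local background subtracted the control median of the components was -0.01 and no longer apart, while C3 was at -0.85 on the control array and turned to 0.53 on the knockout array, a difference of 1.38. C1qb was then at -0.13 and C1qc at 0.05 in control hearts, and Serping1 at -0.06 and Clu at 1.43 in knockout hearts.

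In the Sirt1 knockout hearts, matrix, antigen presentation and inflammatory genes were lower with CR and glucocorticoid-responsive genes higher. Col3a1 was lower at -2.30, H2-Aa at -1.81, Fabp3 (again with its AL signal near the limit of the scanner) at -1.74, the immediate early transcription factor Egr1 at -1.49 and Cd74, the MHC class II invariant chain, at -1.22. Lrrc10, a cardiac leucine-rich repeat protein, was higher by 1.64, Ccn2, a matricellular growth factor, by 1.42, the transcription factor Cebpb by 1.31, Ankrd1 by 1.26 and Sesn1, a stress-responsive regulator of mTORC1, by 1.17. In all, 19 genes were at least 2-fold higher and 13 lower among 12142, against 48 and 66 with a normexp offset of 0 (42.1% higher in place of 59.4%) and 86 and 33 with the local background subtracted (72.3% higher). In the last setting Ccn2 was at 0.57, Egr1 at -0.96, H2-Aa at -0.91 and the apelin receptor Aplnr, at -1.43 otherwise, at -0.42. Rrad, a small GTPase that restrains calcium channels, was at -1.63 and turned to 0.43.

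On the knockout array 14 lists stood apart, 3 higher and 11 lower. Extracellular matrix genes were lower in 25 of 29 (median -0.37), 13 of them by at least 1.5-fold, including Loxl1 at -1.05, Col4a2 at -0.97 and Sparc at -0.90, whereas the protease inhibitor Timp3 was at 1.12. Fibroblast markers, which share collagens with that list, were lower in 12 of 14 (median -0.39). MHC class II genes were lower in 4 of 4 (median -0.67), macrophage markers in 10 of 11 (median -0.28), interferon-responsive genes in 21 of 27 (median -0.10, with B2m at -0.87) and inflammatory genes in 22 of 24 (median -0.16, with the chemokine Ccl2 at -0.73). The fractalkine receptor Cx3cr1, a macrophage marker, was detected in the AL heart only, with a bound of 1.46-fold lower in the CR heart. That bound is open to dye bias and rests on signals near the detection floor. It did not hold with the local background subtracted, where the log2 value was -0.16. Glucocorticoid-responsive genes were higher in 15 of 16 (median 0.46), with Tsc22d3 at 0.98, Map3k6 at 0.73 and Errfi1 at 0.64. FOXO targets were higher in 15 of 19 (median 0.19), with the muscle ubiquitin ligase Fbxo32 at 0.87 and Irs2 at 0.67. Oxidative phosphorylation genes were lower in 45 of 65 (median -0.14), endoplasmic reticulum stress genes in 14 of 21 (median -0.15), endothelial markers in 11 of 15 (median -0.11) and neutrophil markers in 3 of 5 (median -0.22), and liver markers were higher in 3 of 5 (median 0.10). These last 5 and the inflammatory list no longer stood apart with the local background subtracted, and without the detection filter the neutrophil and liver medians reversed (0.034 and -0.0095) and did not stand apart. Sparc was at -0.22, Loxl1 at -0.62, B2m at -0.49, Map3k6 at 0.15, Errfi1 at 0.30 and Irs2 at 0.35 with the local background subtracted.

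**Figure D1:**
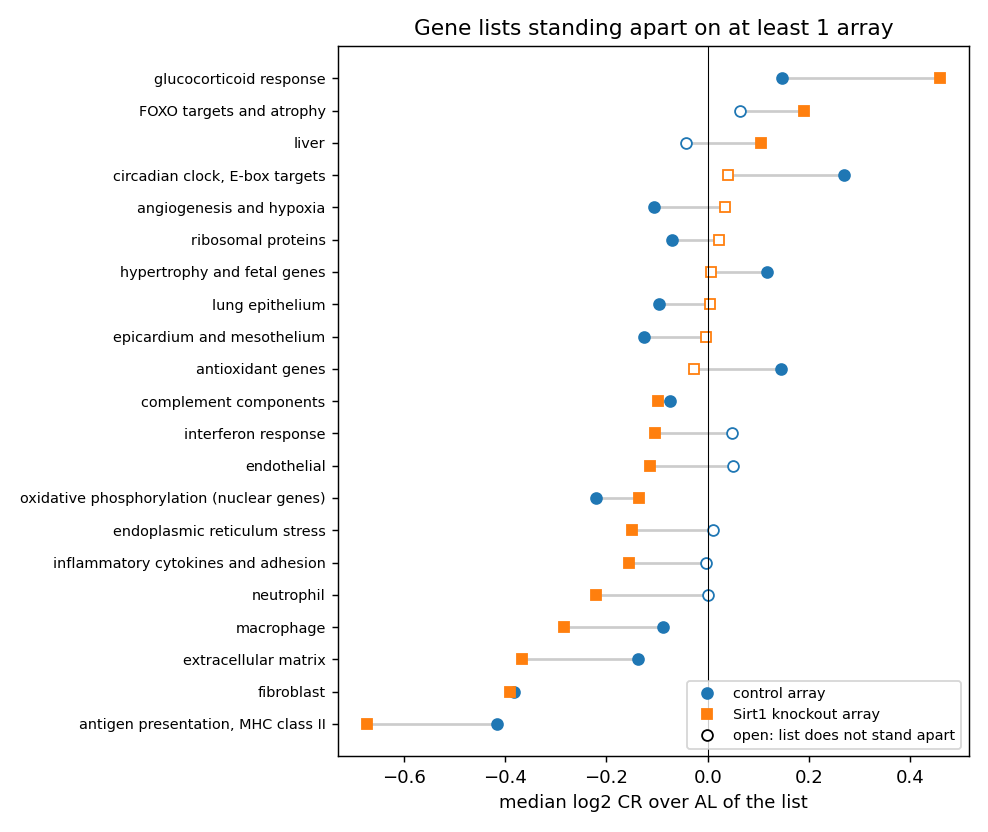
Median log2 CR over AL of each gene list that stood apart on at least 1 array, with control hearts as circles and Sirt1 knockout hearts as squares, and open symbols where the list did not stand apart on that array. Matrix genes lay at -0.14 in control and -0.37 in knockout hearts, and glucocorticoid-responsive genes at 0.15 and 0.46.

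The CR over AL values of the arrays resembled each other. Ankrd1, Ehd4 and Myh7 were higher with CR on both (1.23 and 1.26, 0.88 and 0.98, 0.89 and 0.98), and H2-Aa, Fabp3, Tyrobp and Dcakd lower on both, with Tyrobp at -0.94 and -1.03 and Dcakd at -0.83 and -0.93. Across 11698 genes, which are not independent replicates, r was 0.597 and rho 0.538. At 1.5-fold, 32 genes were higher on both arrays where independent lists would share 0.810, 22 were lower on both where they would share 0.338, and 0 were opposite. With a normexp offset of 0 there were 7 opposite genes (24.0 from independent lists), in the authors' deposited ratios 46 (86.1), and with the local background subtracted 15, more than the 5.32 from independent lists. Because the dyes ran the same way on both arrays, a dye bias of single probes would also give such a resemblance, and r was 0.170 with the local background subtracted, where the control values of Ehd4, Myh7 and Dcakd were 0.40, 0.58 and -0.33.

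**Figure D2:**
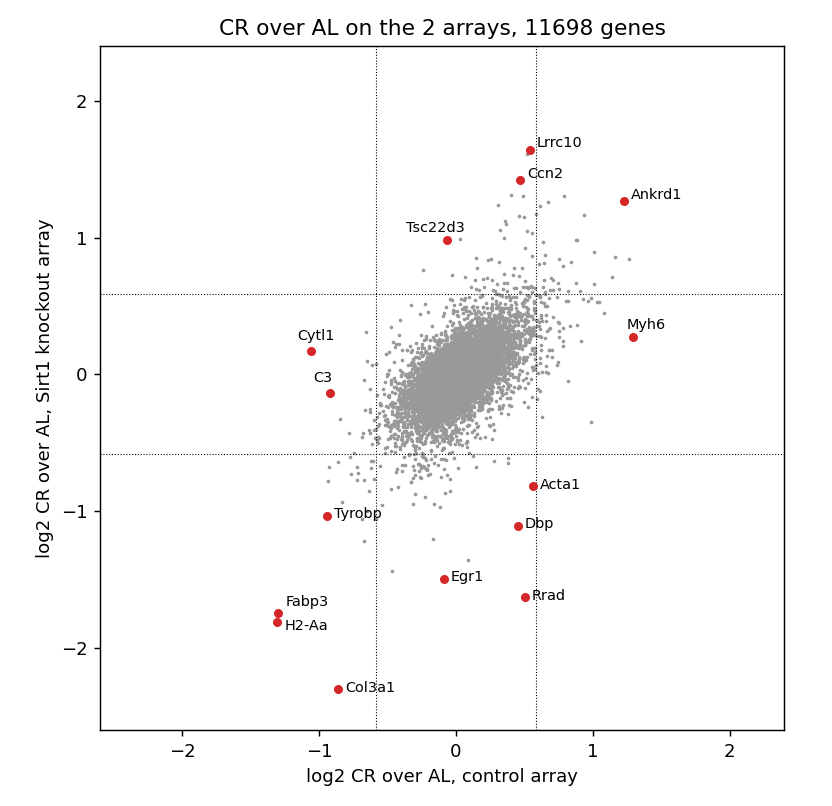
Log2 CR over AL of 11698 genes on the control array (horizontal) and on the Sirt1 knockout array (vertical), 1 point per gene, with dotted lines at 1.5-fold (0.585). C3 lay at -0.92 and -0.14, Col3a1 at -0.86 and -2.30 and Rrad at 0.50 and -1.63.

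The difference of the responses, knockout minus control, removes a dye bias that is equal on both arrays. Col3a1 (-1.44), Egr1 (-1.40) and Dbp (-1.56), a clock output gene at 0.45 in control and -1.11 in knockout hearts, were lower in the knockout response, as was Acta1, skeletal actin, at 0.56 and -0.82 (difference -1.38). Tsc22d3, a glucocorticoid-induced gene, was higher by 1.05, Lrrc10 by 1.10, the phospholipase Pla2g5 by 0.97, and a probe listed as Cyt1, an older name of Cytl1 that was not checked against the probe's sequence, by 1.23. Some of these differences lay mainly in 1 AL heart. Egr1 had a log2 signal of 8.05 in the knockout AL heart and of 6.50, 6.41 and 6.56 in the control AL, control CR and knockout CR hearts. The Cyt1 probe was at 8.18 in the control AL heart and at 7.12, 6.76 and 6.93 in the control CR, knockout AL and knockout CR hearts. In all, 4 genes differed at least 2-fold upward and 10 downward among 11698 (28.6% upward), against 57 and 53 with a normexp offset of 0 and 114 and 51 with the local background subtracted (69.1% upward). Rrad (-2.13) was then at -0.40, Myh6 (-1.02) at -0.21, Col3a1 at -0.93, and Nppa, atrial natriuretic peptide (0.96), turned to -0.38.

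For the difference 23 lists stood apart, 5 higher and 18 lower, and 10 did with the local background subtracted. E-box clock genes were lower in 9 of 11 (median -0.26), with Ciart at -0.77 and Nr1d1 at -0.67, matrix genes in 20 of 29 (median -0.24) and interferon-responsive genes in 23 of 27 (median -0.13). Markers of epicardium and mesothelium were higher in 3 of 4 (median 0.25) and of liver in 4 of 5 (median 0.18), all but Ahsg below the median signal. These 5 lists stood apart under every alternative that gave a value, which for the epicardium and liver lists leaves out genes at or above the median signal, with under 3 members there, although Ciart was at -0.44 and Nr1d1 at -0.29 with the local background subtracted. Glycolysis genes were lower in 20 of 24 (median -0.25), macrophage markers in 8 of 11 (median -0.20) and MHC class II genes in 3 of 4 (median -0.30), and ribosomal proteins were higher in 46 of 52 (median 0.10), none of which stood apart with the local background subtracted. Cardiomyocyte markers were lower in 11 of 15 (median -0.22) and still apart in the authors' deposited ratios at a median of 0.00, but not with median centring in place of loess. In the main setting other lists of cell-type markers stood apart lower as well. They were those of fibroblasts, which share collagens with the matrix list (8 of 14, median -0.13), of smooth muscle and pericytes (8 of 10, median -0.13) and of endothelium (12 of 15, median -0.12). Neutrophil markers also did (3 of 4, median -0.26), but their median was 0.028 without the detection filter. Glucocorticoid-responsive genes did not stand apart (median 0.08, percentile 96.6), although they were higher on the knockout array.

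Between the genotypes, Myl7 and Myl4, myosin light chains of the atria, were lower in the knockout hearts at -3.95 and -2.47 under AL and at -4.06 and -2.71 under CR, while the list of atrial muscle genes did not stand apart (medians -0.09 and -0.15). Myh7, the slow myosin heavy chain, was higher by 2.11 and 2.20, and Acta1 by 2.87 and 1.5. Usp24, a deubiquitinase, was higher by 3.65 and 3.40, the retinoid-binding Rbp3 by 3.34 and 3.49, and Rtp4, a chaperone of membrane receptors, by 2.73 and 2.54. The log2 signal of Rbp3 in the control hearts was 6.235 (AL) and 6.234 (CR), near the lowest detected signals there of 5.84 and 5.88. Rbp3 was at 1.49 and 1.91, and Myl4 at -1.32 under AL, with the local background subtracted. Under AL 57 genes were at least 2-fold higher and 15 lower in the knockout heart among 12783, and under CR 24 and 12 among 11957. With median scaling these were 36 and 34, and 16 and 21, so the balance of higher and lower genes rests on the scaling, and with the local background subtracted they were 596 and 600, and 650 and 558.

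**Figure D3:**
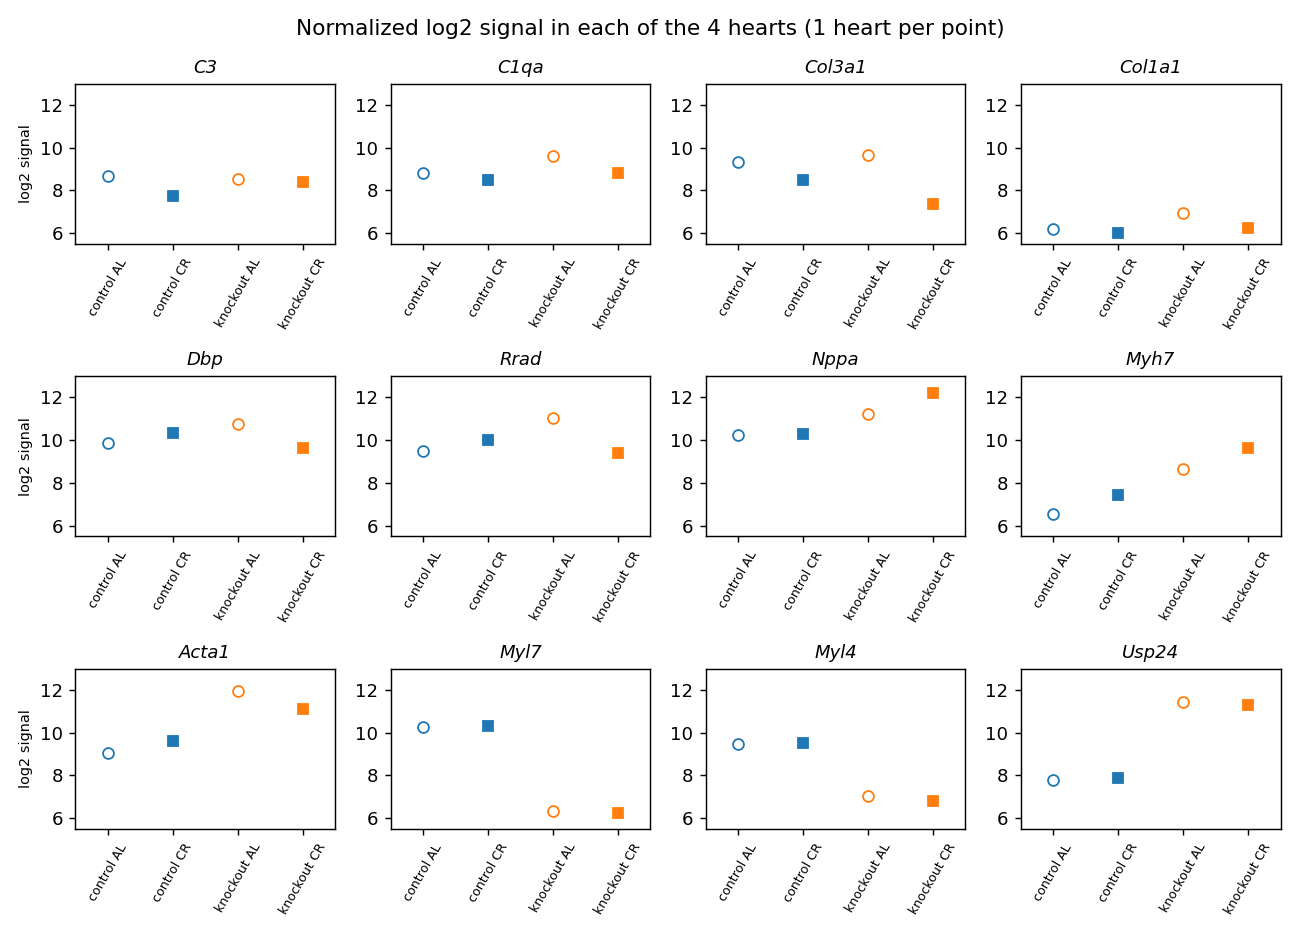
Normalized log2 signal of 12 genes in each of the 4 hearts, 1 heart per point, with AL as open circles and CR as filled squares and control hearts in blue and knockout hearts in orange. C3 lay at 8.65, 7.73, 8.55 and 8.41 in the control AL, control CR, knockout AL and knockout CR hearts.

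Lists also differed between the genotypes, 15 under AL and 14 under CR. Glycolysis genes were higher in the knockout hearts in 23 of 24 under AL (median 0.53) and 21 of 24 under CR (median 0.33), with hexokinase Hk2 at 1.13 and 0.69 and the phosphofructokinase Pfkm at 1.07 and 0.93. With the local background subtracted, Hk2 was at 1.57 under CR and Pfkm at 1.71 and 1.47, whereas Pkm, at 1.55 and 0.90, turned to -1.37 and -0.22. Matrix genes were higher in 26 of 30 under AL (median 0.30) but did not stand apart under CR (22 of 29 higher, median 0.08). Col3a1 was at -1.09 under CR, and at -1.85 with the local background subtracted. Ribosomal proteins were lower in 45 of 52 under AL (median -0.32) and 40 of 52 under CR (median -0.23), and macrophage markers were higher in 12 of 12 under AL (median 0.22) and 9 of 11 under CR (median 0.14). Array and genotype cannot be told apart here, since each genotype was on its own array, and with the local background subtracted 4 and 2 lists stood apart. Of those given here, the glycolysis list under both diets and the matrix and macrophage lists under AL were among them, and the ribosomal list under both diets and the macrophage list under CR were not.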

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

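All the tests of explanations in this part were chosen after the results had been seen.

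Dbp, Rrad and Acta1 were higher with CR in control hearts and lower in knockout hearts, with differences of -1.56, -2.13 and -1.38, and the difference was not tested. Rrad was higher on both arrays with the local background subtracted (0.83 and 0.43, a difference of -0.40). The medians of 8 lists that stood apart in the difference and on at least 1 array also had opposite signs on the arrays, and these differences were not tested either: antioxidant genes (-0.15), endoplasmic reticulum stress (-0.12), interferon response (-0.13), ribosomal proteins (0.10), endothelial (-0.12), neutrophil (-0.26), lung epithelium (0.12) and liver markers (0.18). Several of the medians behind them lay near 0 on 1 array, such as 0.01 for endoplasmic reticulum stress in control hearts.

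Probes without a gene symbol, which no comparison used, also differed with CR. On the control array 13 of 4582 were at least 2-fold higher and 0 lower, and on the knockout array 3 of 4251 were higher and 4 lower. Spots that hold no probe exceeded the blank threshold in 26.0% of cases in the CR channel of the control array and 23.7% on the knockout array, and in 42.5% and 34.2% in the AL channels, so detection just above that threshold does not show that a gene is expressed.

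CR over AL values were alike on the arrays (r 0.597). The values argue against a shift of whole blocks or of neighbouring spots as the cause. A fit within each block left r at 0.607, and neighbouring spots had r of 0.0368 and 0.0513. Subtracting the local background, which followed the spot's own brightness, lowered r to 0.170. A part of the brightness around single spots therefore stays open. Probe-specific dye bias may account for part of it and stays open. In 131 genes with several probes, the same probe had r 0.590 across the arrays and different probes of a gene 0.143, a gap of 0.447 (95% bootstrap interval 0.302 to 0.591), as such a bias would give. The 0.143 had an interval of -0.017 to 0.279, which holds 0. Different probes of a gene had r 0.245 in the genotype comparison under AL, where the dye is shared, and 0.207 on the control array. The interval of their difference, -0.177 to 0.259, is too wide to call them alike or unlike. Probes that measure a gene unequally could give the gap as well, and a shared response to the diet was not tested.

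C3 was lower with CR in the control hearts, and in the knockout hearts it was at -0.14, or at 0.53 with the local background subtracted. A dye bias of its probe that was equal on both arrays would cancel in the difference of 0.78, or 1.38 with the local background subtracted. The pattern was chosen for these values, however, so the size of the difference is no test of it. A bias that differed between the arrays was not examined, so dye bias stays open. Less adipose tissue in the control CR heart could not be judged. The adipocyte median was 0.061 over the 11 markers measured on the control array. Of the 10 detected in all 4 channels, only 1 was both bright and not made by heart tissue itself. Less epicardium or mesothelium could not be judged either: that list, with a difference of 0.25, was singled out because of its values among 18 cell-type lists, 0 of its 4 markers lay above the median signal, and Upk3b (-0.63) and Msln (-0.37) were lower in the control CR heart (-0.19 and -0.18 with the local background subtracted) while Krt19 (-0.05) and Wt1 (0.07) were near 0. A difference between single mice and an effect of Sirt1 also stay open, since each condition had 1 heart.

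Of 11698 genes, 196 differed at least 1.5-fold between the genotypes in the same direction under both diets, and the 2 arrays in place of the genotypes cannot be told apart as their source. DNA of a donor strain around Sirt1 does not hold most of them, because 188 lay on other chromosomes than Sirt1 and 8 on its own (9.59 expected). That count speaks only of where these genes lie, and genes spread evenly over the chromosomes would give a similar one. Donor DNA on other chromosomes was not examined and stays open. Less atrial tissue in the knockout hearts may explain the low Myl7 and Myl4 but stays open: Nppa, another atrial transcript, was higher by 0.99 under AL and 1.95 under CR (0.89 and 0.51 with the local background subtracted), yet the ventricle can also make it, and Myh7 and Acta1 were higher too. The atrial list was lower in 5 of 7 members under AL and 5 of 6 under CR. By at least 1.5-fold, only 2 members, Myl7 and Myl4, were lower and 1, Nppa, was higher under each diet. The list did not stand apart (medians -0.09 and -0.15), although under CR it did with a normexp offset of 0 (-0.31) and without the detection filter (-0.20). An effect of Sirt1 was not tested.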

How the results depend on the processing

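Subtraction of the local background and loess within each block were chosen only after the data had been seen, and the other alternatives were planned. With 1 heart per condition no replicate could be left out. No paired analysis was possible within a genotype because each had 1 array, and a paired test of the diet across both arrays, with 1 residual degree of freedom, was not run. Dim genes limit the comparisons, since a true 2-fold difference among them was returned as under 0.3.

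A named gene's value counted as kept if its sign stayed and it moved by under 0.585. In the comparisons that named the genes, all 410 values were kept with block loess and without background correction. With the local background subtracted 285 were kept, 109 moved and 16 reversed from at least 1.5-fold. The detection filter does not enter a gene's value, so leaving it out could not move these values. Over all comparisons of these genes and the 6 singled out later, 300 of 1260 values changed sign, 28 of them among the 318 of at least 1.5-fold. The cause was not tested for any value in this part.

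With a normexp offset of 0 the genes past 2-fold were 72 (control), 114 (knockout), 110 (difference), 246 (AL) and 169 (CR), in place of 13, 32, 14, 72 and 36. In the authors' deposited ratios they were 371, 365 and 428 for the first comparisons. With the local background subtracted they were 51, 119, 165, 1196 and 1208, and at 1.5-fold they were 146, 184, 104, 556 and 300. The correlation of the responses was 0.485 with offset 0, 0.440 in the authors' deposited ratios and 0.170 with the local background subtracted, in place of 0.597.

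Lists apart in the difference numbered 15 among genes at or above the median signal and 10 with the local background subtracted, in place of 23. With it subtracted, 4 lists stood apart under AL and 2 under CR, in place of 15 and 14. Complement components had a control median of -0.012 with the local background subtracted, and their difference was -0.26 with offset 0, -0.37 in the authors' deposited ratios and -0.31 among brighter genes, where it stood apart.

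List medians that reversed were, without the detection filter, neutrophil (0.034 in knockout, 0.028 in the difference) and liver (-0.0095 in knockout). In the authors' deposited ratios they were the tricarboxylic acid cycle (0.036) and cardiomyocyte (0.0007962, still apart) differences, among brighter genes the inflammatory difference (0.13), and with median scaling the tricarboxylic acid cycle under CR (-0.022, still apart on the higher side). With the local background subtracted they were complement regulators (0.042 in the difference, -0.10 under AL), skeletal muscle under AL (-0.020), and under CR the tricarboxylic acid cycle (-0.37), hypertrophy (-0.22) and MHC class II (0.12).

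The 16 gene values that reversed with the local background subtracted were Nexn in control (-0.89), Rrad (0.43) and Cox8b (1.21) in knockout, Nppa (-0.38), Cxcl9 (0.15) and Pkm (1.14) in the difference, Ndufb4 (1.93), Pkm (-1.37), Fh1 (-0.65), Ndufs1 (-0.70) and Hsp90aa1 (-0.34) under AL, and C3 (-0.089), Ddit4 (-1.02), Pkm (-0.22), Ndufs1 (-0.90) and Jun (-0.11) under CR. Smaller values turned too, such as C3 in knockout (0.53), and so did Glul under CR (-0.11), which was singled out later.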

Other observations

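No test of an explanation was run for the values in this part, and Nampt, Ppargc1a, Sirt5, Txnip, Glul and Sirpa were singled out after their values had been seen.

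Genes of sirtuins, NAD metabolism and mitochondrial biogenesis did not stand apart as a list, with 13 of 21 higher with CR in control hearts (median 0.07) and 16 of 21 in knockout hearts (median 0.03). On each array 1 member was at least 1.5-fold higher, Nampt, the rate-limiting enzyme of NAD salvage, at 0.63 in control and 0.97 in knockout hearts. Below 1.5-fold were Ppargc1a, a coactivator of mitochondrial genes, at 0.49 and 0.51, and the mitochondrial deacylase Sirt5 at 0.57 and 0.35. Ppargc1a was at 0.12 and Sirt5 at 0.37 in control hearts with the local background subtracted. Heat shock genes were higher in the knockout hearts in 13 of 16 under AL (median 0.38) and 14 of 16 under CR (median 0.28), and immediate early genes in 12 of 21 (median 0.10) and 16 of 21 (median 0.17), none of them apart with the local background subtracted.

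Among the 22 genes at least 2-fold apart between the genotypes under both diets, 17 were higher and 5 lower in the knockout hearts. They included Txnip, an inhibitor of thioredoxin and of glucose uptake, at 1.93 under AL and 1.72 under CR, Glul, glutamine synthetase, at 1.30 and 1.60, and Sirpa, a receptor of myeloid cells and of muscle, at 1.30 and 1.30. Growth hormone (Gh), which the pituitary makes, was at 2.16 and 1.84, and Chat, the enzyme of acetylcholine synthesis, at 1.61 and 1.96. In the control hearts Chat had a log2 signal of 6.10 (AL) and 6.12 (CR), near the lowest detected signals. Chat was at 0.42 and 0.90 and Txnip at 0.23 and 1.26 with the local background subtracted, while Glul was at 0.10 and turned to -0.11 under CR.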
